A study of Apis mellifera ligustica with 11 samples.

How the data were processed

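Brain tissue of Apis mellifera ligustica was sampled 1 day before fluvalinate exposure and 10, 20 and 30 days after it. Per the labels, the glands that make royal jelly and the pigments were taken off before total RNA was extracted with Trizol, and an Illumina HiSeq instrument was used. The values are FPKM per gene and library, as deposited by the authors and rounded to 2 decimals; the unit is stated per the file headers, and FPKM relates fragments to transcript length and to the mapped fragments of the library. The submitters' processing notes name fastp 0.18.0, HISAT2 2.1.0 and StringTie, with no statement of what each did. The genome build and annotation are not given in the sources used here, and neither is whether strand was used, so overlapping genes may share reads. No further scaling between libraries is stated in the sources used here.

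The table holds 9974 rows, of which 9935 carry an NCBI gene number and 39 an identifier of StringTie's form. All 9935 numbers matched the RefSeq gene table of the assembly Amel_HAv3.1, which served only to check names; genes are named by the symbol in the deposited table. No coordinates or transcript lengths are used, because the authors' build is not named. The table has 12 FPKM columns and 1 of them was not used here. The control-titled libraries are all labelled as taken before exposure and serve as the reference.

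FPKM keep no read counts, and low values did not fall on steps of whole reads when compared between libraries, so the depth of each library is unknown and no counting error can be given. Precision therefore comes from the spread between libraries. Summed FPKM ranged from 264416 (before-exposure replicate 1) to 468358 (day 10 replicate 2), and the 10 most abundant genes made up between 13% and 52.1% of the sum. Between 7626 and 7944 genes reached 1 FPKM in a library. No pair of libraries shared identical nonzero values in more than 1.28% of genes, so none looked like a library deposited again. Libraries of a group correlated across genes with r between 0.949 and 0.979 on the log2 scale, and libraries of different groups between 0.898 and 0.982.

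The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend in the empirical Bayes step, on the 7830 genes with a mean of at least 1 FPKM over the 11 libraries. All 11 libraries entered 1 fit of group means with 7 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg within each comparison, with calls under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and each is given with its moderated standard error. The comparisons were each exposed day against before exposure, the exposed days against each other, and the mean of the 3 exposed days against before exposure. Means are given with the SD between libraries. On simulated data with 7830 genes, 77%, 86% and 88% of 2-fold changes were recovered for days 10, 20 and 30 against before exposure, 98%, 98% and 100% of 4-fold changes, and 5 simulations without change gave 0 calls. The simulated genes varied independently and whole libraries did not differ, unlike in the real data, and the lowest genes were left unchanged. These shares therefore do not tell how many real changes were missed or how many calls are false.

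Gene lists (33) were fixed before the data were examined, from symbols and descriptions, along with the comparisons, tests and naming rule, and 32 had at least 5 measured genes. They cover detoxification, stress, immunity, neuronal function, metabolism, chemosensation, hormone signalling, markers of other tissues (hypopharyngeal gland, fat body, photoreceptor, muscle, glia, haemocyte) and signs of library quality (mitochondrially encoded transcripts, histones). Matching by words brings in some genes that do not do what the list says, such as DNA-dependent and AMP-activated kinases among learning kinases, and some genes count in 2 lists. Of the 61 genes of the nuclear oxidative phosphorylation list 4 also count in another list, as do 4 of the 9 mitochondrially encoded transcripts. These 2 lists may therefore share genes, and either name may not hold for all of its members. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry.

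Named genes follow a rule fixed at the same time. For each day against before exposure these are the 12 genes with the largest change in each direction that passed, whose libraries do not overlap between the groups, with a mean of at least 5 FPKM in the higher group and a known name. Where none passed, the 5 with the smallest p in each direction are given as values. The same holds for the exposed days with 5 genes per direction, and each list gives up to 4 members past the threshold or else up to 2 as values. Genes outside the rule, such as Hbg3, Mrjp5, Mrjp6, LOC406081 and LOC406114 of the gland list, kayak, and Hsc70-4, LOC725114 and Lop1, were chosen after their values were seen.

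Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, array quality weights, a robust fit, only the libraries compared, the replicate number as a block, and each library left out in turn. The gland level (mean log2 of Mrjp1 to Mrjp7) or the mitochondrial level (mean log2 of the mitochondrially encoded transcripts relative to the median gene) as a covariate, and for lists also median-of-ratios scaling, were added after seeing the data. Leaving out a day 10 library leaves 1, which is then assumed to vary like the other groups. Correlations between comparisons that share libraries were set beside 50 simulations of unchanged groups, again with genes that varied independently.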

Results

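The series measured mRNA in brain tissue of the Italian honeybee, Apis mellifera ligustica, around exposure to fluvalinate. Fluvalinate is a pyrethroid that beekeepers use inside hives against mites, and pyrethroids act on voltage-gated sodium channels of nerve cells. The 11 libraries comprise 3 taken 1 day before exposure, 2 from day 10, 3 from day 20 and 3 from day 30, and mite treatment was repeated every 7 days per the labels. The question was how brain gene expression differs after the exposure begins. Unexposed libraries from days 10, 20 and 30 were not analysed here, so exposure and the time that passed cannot be separated in any comparison. The treatment protocol describes control and test sets, so the control-titled libraries may also differ from the exposed ones by set. Nothing in the labels says that the libraries of a group came from separate colonies or pools of bees, so p-values measure only the spread between these libraries.

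Transcripts of the hypopharyngeal gland, the head gland of worker bees that makes royal jelly, took up very different parts of the libraries. The summed FPKM of Mrjp1 to Mrjp7, the major royal jelly protein genes, was 4662, 12863 and 6994 in the 3 libraries before exposure. It was 126260 and 94231 at day 10, 44155, 85199 and 61935 at day 20, and 4234, 36823 and 9049 at day 30. These sums were between 1.5% (day 30 replicate 1) and 27% (day 10 replicate 2) of all FPKM in a library. Within each of the 4 sampling times the sum was highest in replicate 2, and it was lowest in replicate 1 at the 3 times other than day 10, whose libraries are replicates 2 and 3. The labels state that royal jelly glands were taken off the brains before extraction, and Mrjp1 is also known to be transcribed in the brain itself. Day 10 replicate 2 stood farthest from the other libraries, with a score of 41.7 on the first principal component, which held 36.4% of the variance. Day 10 replicate 3 followed at 19, and the other 9 libraries lay between -20.7 and 10.2.

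**Figure D1:**
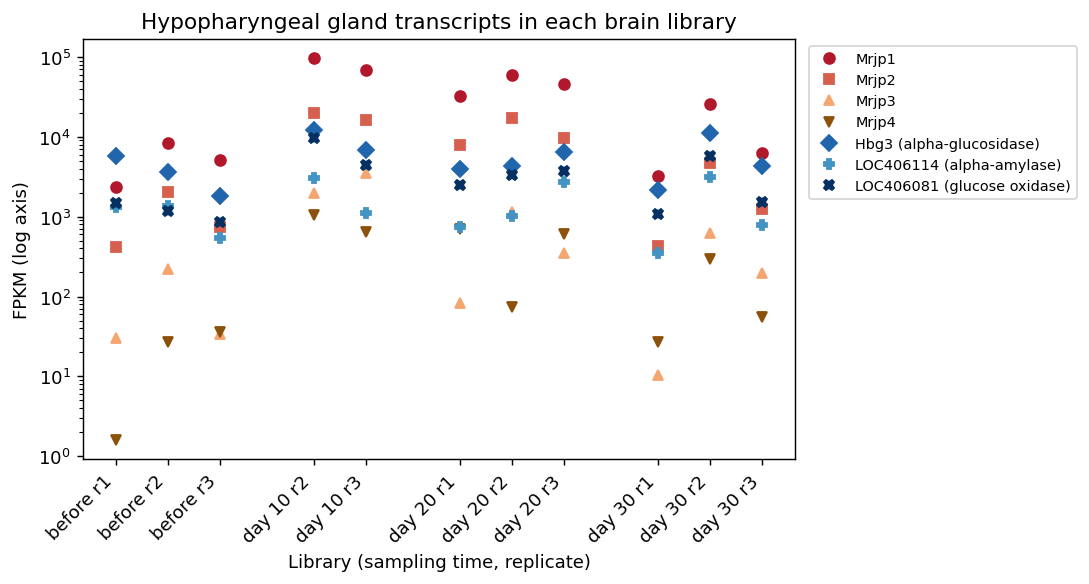
FPKM of 4 major royal jelly protein genes (Mrjp1 to Mrjp4) and 3 gland enzymes in each of the 11 libraries, on a log axis, with 1 point per gene and library. Mrjp1 lay between 32856 and 96898 FPKM in the 5 libraries of days 10 and 20 and between 2347 and 8378 FPKM before exposure, and day 30 replicate 2 (25775 FPKM) lay above day 30 replicates 1 and 3.

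In the brains of day 10, against those taken before exposure, 6 royal jelly protein genes were higher, 17 of 20 voltage-gated ion channel genes were lower, and of 44 synaptic genes 22 were lower and 3 higher. Neither of these 2 neuronal lists passed with a correlation between genes estimated from the data (adjusted p = 0.462 and 0.479). Mrjp1 rose from 5268 ± 3019.9 FPKM (SD, n = 3) to 82896 ± 19802 FPKM (SD, n = 2), and Mrjp2, Mrjp3, Mrjp4, Mrjp7 and Mrjp9 rose as well. Para, the sodium channel on which pyrethroids act, fell from 72.2 ± 8.02 to 33.1 ± 10.8 FPKM. brp (bruchpilot), a scaffold protein of presynaptic active zones, fell from 32.3 ± 2.97 to 11.3 ± 3.56 FPKM. Of 7830 genes tested with limma, 1500 passed an adjusted p of 0.05, 174 higher and 1326 lower, and 100 and 174 of these differed by at least 2-fold. The median of all genes lay at -0.18 on the log2 scale at day 10 and moved to 0.02 with median-of-ratios scaling. The log2 changes below are therefore given relative to the median gene of their comparison. The p-values and calls beside them test the changes as deposited, before this subtraction, unless another scaling is named. With median-of-ratios scaling 777 genes passed, 311 higher and 466 lower. That is 40% higher against 11.6% as deposited. Without day 10 replicate 2, which leaves 1 library at day 10, 2 genes passed with limma (1288 at an unadjusted p of 0.05). The fall was larger in day 10 replicate 2: the 1326 lower genes had a median change of -0.89 in it and of -0.53 in replicate 3. All genes had medians of -0.24 and -0.12 in these 2 libraries. The count of genes passing was 917 without before-exposure replicate 3 and 958 without before-exposure replicate 1. With the gland level as a covariate, an alternative chosen after seeing the data, limma called 0 genes, with 782 at an unadjusted p of 0.05. With the level of the mitochondrially encoded transcripts as a covariate, also chosen after seeing the data, it called 2 genes, LOC724936 (uncharacterized) and LOC725131 (futsch), with 1429 at an unadjusted p of 0.05.

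**Figure D2:**
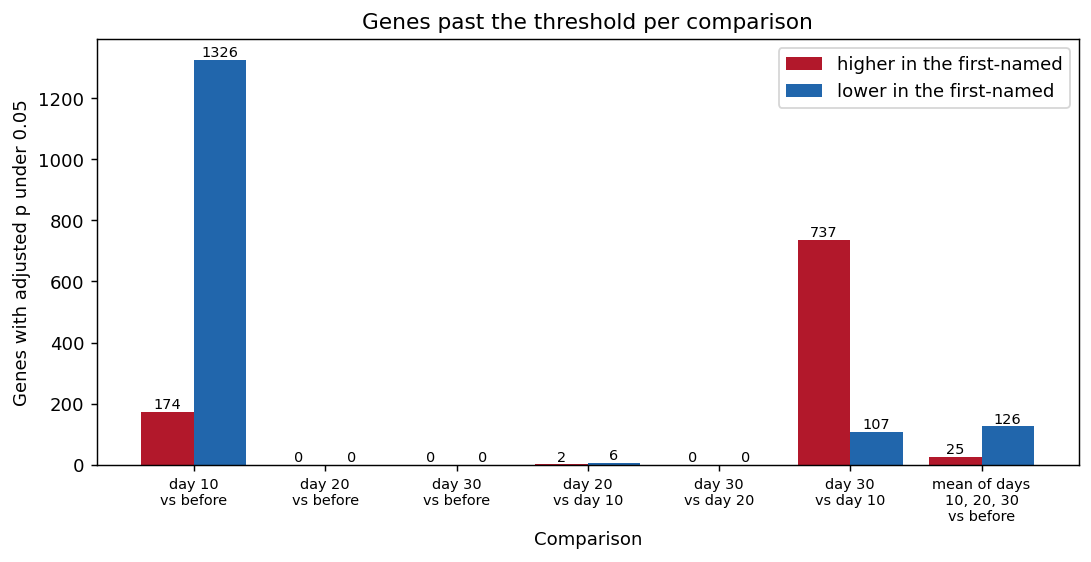
Number of genes with adjusted p under 0.05 in each comparison, with 1 bar for genes higher and 1 for genes lower in the first-named group. Day 10 against before exposure has 174 higher and 1326 lower genes, day 30 against day 10 has 737 and 107, and the bars of days 20 and 30 against before exposure are at 0.

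The 12 named genes with the largest rise at day 10 were led by royal jelly proteins. Mrjp4 changed by 6.06 ± 1.23 (SE) on the log2 scale relative to the median gene, Mrjp3 by 5.58 ± 1.44, Mrjp2 by 4.57 ± 0.84, Mrjp7 by 4.45 ± 0.97 and Mrjp1 by 4.32 ± 0.87. Their adjusted p-values lay between 0.00732 and 0.0225. The major royal jelly protein genes are a family of similar sequences, so how the authors' pipeline divided reads among them is uncertain. LOC551044, a glucose dehydrogenase, rose from 6.98 ± 1.60 to 165 ± 24.4 FPKM, and LOC725215, venom acid phosphatase Acph-1, from 4.08 ± 4.24 to 77.5 ± 9.01 FPKM. LOC724239, a kynurenine/alpha-aminoadipate aminotransferase, rose by 4.06 ± 0.88. The other 4 were the cytochrome P450 LOC413083 (6a14, 5.27 ± 1.60), the UDP-glucuronosyltransferase LOC725017 (2B15, 5.44 ± 1.63), LOC406105 (esterase A2, 5.23 ± 1.63) and the ABC transporter LOC725051 (multidrug resistance-associated protein 4, 4.13 ± 1.10). All 4 had adjusted p-values between 0.0265 and 0.048, and all 4 were highest in replicate 2 at each of the 4 sampling times. LOC413083 stood at 57.4 FPKM in before-exposure replicate 2 against 4.63 and 5.99 FPKM in replicates 1 and 3, at 62.2 against 8.41 and 6.90 FPKM at day 20, at 463 against 3.57 and 11.98 FPKM at day 30, and at 548 and 371 FPKM in day 10 replicates 2 and 3. Without before-exposure replicate 1 the adjusted p of LOC413083 was 0.115, that of LOC725017 0.121, that of LOC406105 0.129, that of LOC725051 0.0786 and that of Mrjp3 0.0674, so these 5 calls were lost. Their log2 changes as deposited were then 4.48, 4.21, 4.28, 3.48 and 4.90, in the same order. With the replicate number as a block all 5 passed with limma (adjusted p between 0.00976 and 0.0177). With the gland level as a covariate, chosen after seeing the data, their log2 changes, here not relative to the median gene, turned to -1.52 (LOC413083), -0.98 (LOC725017), -1.65 (LOC406105) and -0.63 (LOC725051).

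The 12 named genes with the largest fall at day 10 included several with known roles in neurons. LOC411420, adenosine receptor A2b, fell from 14.9 ± 1.41 to 2.31 ± 2.09 FPKM (adjusted p = 0.00563). LOC410497, a G protein beta subunit, changed by -1.89 ± 0.41 and LOC725131, the microtubule-associated protein futsch, by -1.40 ± 0.16 (adjusted p = 0.00202). AChE-2, an acetylcholinesterase, which breaks down acetylcholine, fell from 74.5 ± 7.89 to 27.1 ± 12.3 FPKM. LOC410689 (ELAV-like protein 2, an RNA-binding protein, -1.32 ± 0.22), LOC410779 (neuroligin 2, a synaptic adhesion protein, -1.26 ± 0.26), LOC412777 (the sodium/potassium/calcium exchanger Nckx30C, -1.28 ± 0.32) and LOC413633 (the kinase BRSK2, -1.25 ± 0.26) fell too. The remaining ones were brp, CPR6 (cuticular protein 6, -1.61 ± 0.28), LOC409897 (a multidrug resistance-associated protein, -1.55 ± 0.28) and LOC100577778 (described as fibronectin-binding protein PlpA, -1.50 ± 0.26). No value of either day 10 library overlapped the before-exposure libraries in any of these 12 genes, which the rule for naming genes required.

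**Figure D3:**
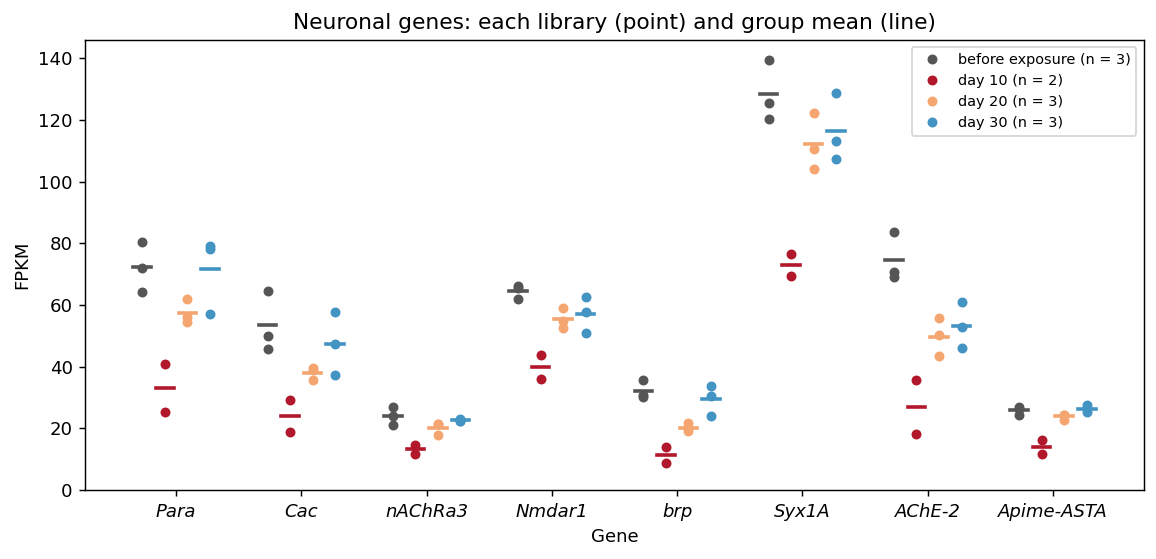
FPKM of 8 genes in each library (points) and the group means (lines) before exposure (n = 3) and at days 10 (n = 2), 20 (n = 3) and 30 (n = 3). In each of the 8 genes both day 10 libraries lay below all 3 libraries taken before exposure, as in Para with 25.4 and 40.7 against 64.3 to 80.3 FPKM. The 8 were picked among genes called lower at day 10, so this separation follows largely from the choice.

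Among the gene lists fixed before the data were examined, 5 of neuronal function were called downward by camera at day 10 as deposited, and none of the 5 with a correlation between genes estimated from the data (adjusted p = 0.462 to 0.514). With median-of-ratios scaling, chosen for the lists after seeing the data, and with quantile normalization 8 were, the other 3 being those of glia (adjusted p = 0.0497 and 0.0405), hormone signalling (0.0337 and 0.0392) and odorant and gustatory receptors (0.0293 and 0.0261), all at the preset correlation of 0.01. Of 20 voltage-gated ion channel genes 17 fell and none rose, with a median of -0.68 relative to all genes; adjusted over the list alone 19 fell and 1 rose. Besides Para these included Cac (the calcium channel cacophony, 53.5 ± 9.77 to 24.0 ± 7.29 FPKM), LOC551883 (a T-type calcium channel, -0.88 ± 0.17) and LOC100577254 (a KQT potassium channel, -0.85 ± 0.18). Of 49 neurotransmitter receptor genes 31 fell and none rose (34 and 0 adjusted over the list alone), among them nAChRa3 (a nicotinic acetylcholine receptor subunit, -0.64 ± 0.15), Nmdar1 (-0.51 ± 0.13), LOC412818 (NMDA receptor 2, -0.86 ± 0.19) and LOC406124 (a GABA receptor beta subunit, -0.90 ± 0.18). Of 44 synaptic vesicle and active zone genes 22 fell and 3 rose (23 and 4 adjusted over the list alone). Syx1A (syntaxin 1A, -0.63 ± 0.13) and LOC411114 (SNAP-25, -0.82 ± 0.17), parts of the vesicle fusion machinery, fell, and LOC411186, described as synaptic vesicle glycoprotein 2C, rose from 1.23 ± 0.56 to 15.6 ± 2.84 FPKM. Of 14 neuropeptide precursors 8 fell and none rose (11 and 0 adjusted over the list alone), including LOC113218809 (diuretic hormone class 2, -0.81 ± 0.16), Apime-ASTA (allatostatin A, -0.67 ± 0.14), Tk (tachykinin, -0.43 ± 0.14) and LOC725616 (allatostatin C, -0.52 ± 0.17). Of 24 learning and memory kinase and cAMP signalling genes 9 fell and 1 rose (11 and 1 adjusted over the list alone), among them Camkii (-0.75 ± 0.16), Pkc (-0.61 ± 0.16) and LOC411288 (a cAMP phosphodiesterase, -0.63 ± 0.15). The camera test of limma with a preset correlation of 0.01 gave adjusted p = 8.43e-07 for the channels, 1.04e-06 for the receptors, 0.013 for the synaptic genes, 0.00161 for the neuropeptides and 0.0182 for the kinases. None of the 5 passed when the correlation between genes was estimated from the data, where the adjusted p with an estimated correlation was 0.462 for the channels and neuropeptides, 0.479 for the receptors and synaptic genes and 0.514 for the kinases. With median-of-ratios scaling the medians of all 5 lists stayed below 0. The royal jelly transcripts made up 27% and 23.9% of all FPKM in the 2 day 10 libraries, and also 23.9% in day 20 replicate 2. With the gland level as a covariate, chosen after seeing the data, 6 lists of any kind were called at day 10, 5 of them among the 17 called without it. Mitochondrially encoded transcripts, a sign of library quality, had a median of 1.04 relative to all genes at day 10, though 4 of the 9 also count in another list. Their mean level relative to the gene means and the median gene was 1.07 and 0.13 in day 10 replicates 2 and 3 and -1.10, 0.18 and -0.39 in before-exposure replicates 1, 2 and 3. Within sampling times it correlated with that of the channel list at r = -0.88. With this level as a covariate, chosen after seeing the data, camera called 13 lists, 5 of them downward, among which were the channels, receptors, synaptic genes and neuropeptides.

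Single genes of hormone signalling, the clock, glia and chemoreception fell as well, in lists that camera did not pass as deposited and fry did. Of 21 genes of juvenile hormone, ecdysone and insulin signalling 8 fell (11 adjusted over the list alone), among them E75 (-0.57 ± 0.12), Br-c (broad-complex, -0.83 ± 0.20) and LOC411297 (the insulin-like peptide receptor, -0.47 ± 0.17), with camera adjusted p = 0.0531 (adjusted p = 0.479 with an estimated correlation). Of 6 circadian clock genes Per (-0.82 ± 0.21) and LOC411534 (Clock, -0.42 ± 0.14) fell (3 adjusted over the list alone), with camera adjusted p = 0.167 (adjusted p = 0.479 with an estimated correlation). Of 11 glial markers 4 fell (5 adjusted over the list alone), including the glutamate transporters Eaat-2 (-0.68 ± 0.21) and LOC409919 (-0.56 ± 0.19), with camera adjusted p = 0.0513 (adjusted p = 0.479 with an estimated correlation). Of 9 odorant and gustatory receptors Or35, Or37 and Gr10 fell, the same number as adjusted over the list alone, and the camera adjusted p was 0.0769 (adjusted p = 0.462 with an estimated correlation). limma's fry, which tests whether the genes of a list move one way on balance, passed these 4 lists and the 5 neuronal lists at day 10, with adjusted p between 0.000642 and 0.021. All 9 were downward. Unlike camera, fry does not compare a list with the other genes, and it was run only on values as deposited. The fall of the median gene (-0.18) therefore favours downward calls by fry. Of all genes tested 16.9% were called lower.

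Camera called 12 lists upward at day 10, with the smallest p for ribosomal proteins, hypopharyngeal gland markers, lipid synthesis and the proteasome. The hypopharyngeal gland list had 9 of 25 genes higher and 1 lower, unchanged when adjusted over the list alone, a median of 0.69 relative to all genes and camera adjusted p = 2.22e-08 (adjusted p = 0.462 with an estimated correlation). It includes glucose dehydrogenases and lysosomal alpha-glucosidases that are not specific to the gland. LOC406081 (glucose oxidase) rose within it from 863 to 1490 FPKM before exposure to 4497 and 9608 FPKM, while Hbg3, an alpha-glucosidase, had a log2 difference of 1.44 ± 0.65 (SE, not relative to the median gene, adjusted p = 0.144) and Mrjp6 one of -0.02 ± 0.86 (adjusted p = 0.99). Of 32 lipid synthesis genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 3.89e-05 (adjusted p = 0.462 with an estimated correlation). They included LOC412815 (fatty acid synthase, 197 ± 32.1 to 513 ± 85.7 FPKM), FAR1 (fatty acyl-CoA reductase 1, 1.44 ± 0.25), LOC411983 (a putative fatty acyl-CoA reductase, 1.29 ± 0.22) and LOC724552 (a fatty acid elongase, 2.44 ± 0.54). Of 79 cytosolic ribosomal protein genes none passed singly, in all genes or adjusted over the list alone, and their median was 0.34 relative to all genes with camera adjusted p = 1.57e-10 (adjusted p = 0.479 with an estimated correlation). Of 35 proteasome genes LOC411520 (subunit beta type-4, 1.00 ± 0.21) rose (0 adjusted over the list alone), with camera adjusted p = 4.5e-05 (adjusted p = 0.479 with an estimated correlation). The 9 genes of the unfolded protein response (0.000728), in which LOC552645 (mesencephalic astrocyte-derived neurotrophic factor, 0.84 ± 0.19) rose in both adjustments, and 9 mitochondrially encoded transcripts (0.000187), of which none passed singly in either adjustment, also passed camera, with adjusted p = 0.462 for both with an estimated correlation.

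Detoxification and defence genes moved both ways at day 10. Of 30 cytochrome P450 genes 3 rose and 1 fell (1 and 0 adjusted over the list alone), with camera adjusted p = 0.0145 (adjusted p = 0.462 with an estimated correlation). LOC551560 (6k1) went from 7.78 ± 1.88 to 16.6 ± 1.77 FPKM and LOC408452 (9e2) from 722 ± 101 to 467 ± 42.1 FPKM. Among 5 glutathione S-transferases LOC410837 rose and GstS1 fell (both also adjusted over the list alone), of 8 carboxylesterases LOC410187 (esterase E4) fell in both adjustments, and of 37 UDP-glycosyltransferases and ABC transporters 2 rose and 4 fell (1 and 3 adjusted over the list alone). Their camera adjusted p-values were 0.575, 0.575 and 0.527. Of 19 immune genes 3 rose and 2 fell in both adjustments, with camera adjusted p = 0.0513. Def1, an antimicrobial peptide, rose from 690.2 ± 179.7 to 4419 ± 1648 FPKM, LOC409204 (phenoloxidase-activating factor 2) by 2.51 ± 0.64 and LOC113218576 (lysozyme-like) by 0.89 ± 0.20. Def1 also stood at 3817 FPKM in day 30 replicate 2 against 503 and 726 FPKM in replicates 1 and 3. Mrjp1 likewise stood at 25775 FPKM there against 3205 and 6270 FPKM. Whether the rise of Def1 is apart from that of the gland transcripts was not tested. LOC409204 also counts in the haemocyte list, where it alone of 5 genes rose (2 adjusted over the list alone) and camera gave adjusted p = 0.00638 (adjusted p = 0.462 with an estimated correlation).

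The other lists with a camera call at day 10 were nuclear oxidative phosphorylation (0.0204, 0 of 61 genes in either adjustment), photoreceptor and eye pigment markers (0.045, 1 of 26 genes higher and 3 lower), muscle markers (0.045, 0 of 26 higher and 2 lower) and histones (0.0241, 1 of 22 higher and 1 lower). Their adjusted p with an estimated correlation was 0.725, 0.514, 0.663 and 0.552. All 4 were upward by camera, yet fry put the first 3 downward, and photoreceptor, muscle and cytochrome P450 lists lost the call with median-of-ratios scaling, where the antioxidant list gained one (adjusted p = 0.0223). Adjusted over the list alone these counts were equal, except that no histone gene fell. The 2 muscle genes were titins, LOC408677 and LOC724192. The lower gene of the histone list was Hiscl1, a histamine-gated channel that matched the list by name only, and the higher one was LOC725344, a histone H2B. Antioxidant enzymes (camera adjusted p = 0.0926, 0 of 23), heat shock proteins (0.585, 1 of 20 lower, LOC724405), glycolysis and tricarboxylic acid cycle (0.585, 2 of 31 lower), autophagy and apoptosis (0.604, 1 of 21 higher and 3 lower), odorant-binding and chemosensory proteins (0.0531, 1 of 15 higher and 2 lower), cuticle proteins (0.483, 2 of 21 lower) and fat body and haemolymph markers (0.585, 1 of 11 higher and 1 lower) did not pass. Adjusted over the list alone these counts were equal, except that no heat shock or glycolysis gene fell. Camera, which compares a list with all other genes, pointed up while the mean change of the list was below 0 for glutathione S-transferases, carboxylesterases, antioxidant enzymes, heat shock proteins, glycolysis, autophagy and cuticle proteins. In the fat body and UDP-glycosyltransferase lists the median lay below and the mean above 0 as deposited, and camera pointed up. The higher fat body gene was A4, an apolipophorin-III-like protein, with 667 and 270 FPKM at day 10 and 582 FPKM in day 30 replicate 2, against 16.9 to 51.4 FPKM in the other 8 libraries. Only 3 activity-regulated transcription factors were measured, too few to test as a list. Among them LOC724169 (kayak) had a log2 difference of -0.55 as deposited (adjusted p = 0.0607).

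**Figure D4:**
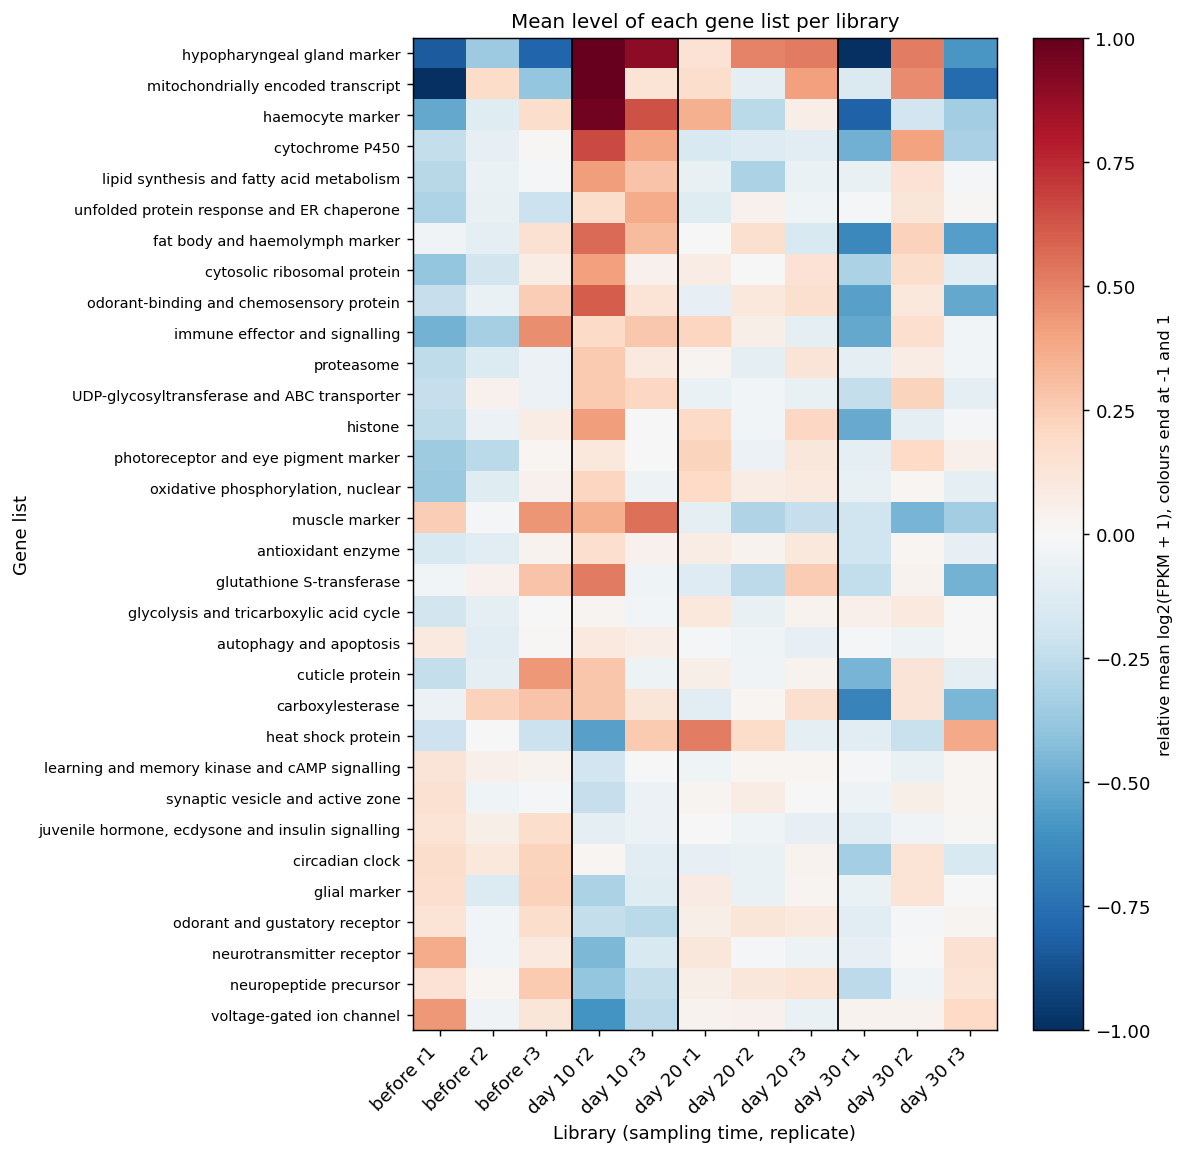
Mean log2(FPKM + 1) of each of 32 gene lists in each library, relative to the mean of the genes over the 11 libraries and to the median gene of the library, from blue (lower) to red (higher). The hypopharyngeal gland list stood at 1.32 and 0.90 in the day 10 libraries and between -0.83 and -0.36 before exposure, while the voltage-gated ion channel list stood at -0.59 and -0.26 against -0.04 to 0.43.

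At day 20, against before exposure, no single gene passed with limma, and the values with the smallest p included genes of the gland and of muscle. LOC551044, the glucose dehydrogenase, stood at 60.4 ± 25.3 FPKM against 6.98 ± 1.60 before exposure (adjusted p = 0.084), and Mrjp2 at 11584 ± 5041 against 1060.0 ± 844 FPKM (adjusted p = 0.183). LOC725215 (Acph-1, 3.54 ± 0.65), LOC411186 (synaptic vesicle glycoprotein 2C, 2.25 ± 0.36) and LOC724471 (a phosphoinositide phospholipase C, 1.78 ± 0.29) were the other upward values. TpnCI, troponin C of muscle, stood at 12.2 ± 3.78 against 28.3 ± 1.47 FPKM and Cyp6as5, a cytochrome P450, at 18.5 ± 1.47 against 42.4 ± 6.08 FPKM, both with adjusted p = 0.084. LOC409740 (alpha-tocopherol transfer protein-like, -1.70 ± 0.33), LOC411564 (nose resistant to fluoxetine protein 6, -1.12 ± 0.22) and LOC725878 (held out wings, -0.46 ± 0.10) were the other downward values. At an unadjusted p of 0.05, 774 genes passed where chance gives 392. In simulated data with independent genes 86% of 2-fold changes were recovered in this comparison. That share does not tell how many real changes were missed, as LOC551044 did not pass with a 7.3-fold difference. With the replicate number as a block 11 genes passed, among them LOC551044, LOC725215 and Mrjp2 (adjusted p = 0.0146 each) and LOC411186, TpnCI and LOC411564 (0.0421 each). The count was 1 without before-exposure replicate 2, 1 without day 20 replicate 1, 14 without day 30 replicate 2 and 2 without day 30 replicate 3.

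As a list, muscle markers were lower at day 20, with all 26 genes below their before-exposure level, a median of -0.45 relative to all genes and camera adjusted p = 6.48e-11 (adjusted p = 0.446 with an estimated correlation). Of these, 11 fell when adjusted over the list alone and 0 over all genes. Cytosolic ribosomal proteins (2.52e-14), nuclear oxidative phosphorylation (2.12e-13) and hypopharyngeal gland markers (4.41e-08) led the 11 lists that moved up, with adjusted p = 0.707, 0.625 and 0.446 with an estimated correlation. Adjusted over the list alone, 6 gland genes rose and no ribosomal or oxidative phosphorylation gene did. Adjusted likewise, 4 cytochrome P450 genes fell and 1 histone gene rose. The other lists moving up were photoreceptor markers (0.000192), proteasome (0.000888), mitochondrially encoded transcripts (0.000888), heat shock proteins (0.0023), antioxidant enzymes (0.00316), histones (0.00316), glycolysis and tricarboxylic acid cycle (0.0331) and the unfolded protein response (0.0423). Downward lists besides muscle were juvenile hormone, ecdysone and insulin signalling (0.00277), voltage-gated ion channels (0.00572), neurotransmitter receptors (0.00889), circadian clock (0.0364) and learning and memory kinases (0.0496). With an estimated correlation the adjusted p of these 17 lists lay between 0.446 and 0.726, so none passed, and fry passed the clock and hormone signalling lists (adjusted p = 0.0425 and 0.0456). The other 15 lists had camera adjusted p-values from 0.0506 (immune genes) to 0.978 (cytochrome P450). The immune and haemocyte lists had a mean above and a median below 0 as deposited, and camera pointed up for 3 lists with a mean below 0 (odorant-binding proteins, odorant receptors and cuticle proteins). Without before-exposure replicate 1 the number of lists was 8. With the gland level as a covariate, chosen after seeing the data, 12 lists were called, 1 upward and 11 downward, among them 4 of the 17 called without it, and the ribosomal list turned to a downward call (adjusted p = 0.0289).

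At day 30, against before exposure, again no gene passed with limma, and the values with the smallest p included genes of hormone synthesis and muscle. LOC724216, juvenile hormone acid O-methyltransferase, an enzyme of juvenile hormone synthesis, stood at 11.4 ± 3.00 FPKM against 45.1 ± 6.30 before exposure (-1.94 ± 0.29 on the log2 scale, adjusted p = 0.101), lower in 3 of 3 libraries. TpnCI stood at 13.5 ± 2.44 against 28.3 ± 1.47 FPKM (adjusted p = 0.138), and LOC409602, a circadian clock-controlled protein, at 24.8 ± 2.56 against 50.2 ± 15.6 FPKM. LOC412209 (cytochrome P450 6a17, -0.67 ± 0.12) and LOC411564 (-1.26 ± 0.22) were also among the lowest p-values. Upward values were those of LOC724951 (a lysophosphatidic acid acyltransferase, 1.47 ± 0.25), LOC724471 (1.72 ± 0.29), LOC552447 (clavesin-2, 1.62 ± 0.35), LOC408361 (alpha-tocopherol transfer protein-like, 1.13 ± 0.25) and LOC412162 (gudu, 2.36 ± 0.53), with adjusted p between 0.101 and 0.241. At an unadjusted p of 0.05, 562 genes passed where chance gives 392. In simulated data with independent genes 88% of 2-fold changes were recovered in this comparison, which does not tell how many real changes were missed. The count was 2 without before-exposure replicate 1, 1 without before-exposure replicate 2, 7 without day 20 replicate 1, and 1 without day 30 replicate 1 or replicate 2.

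Muscle markers were the list with the smallest p at day 30. All 26 lay below their before-exposure level, 14 fell adjusted over the list alone and 0 over all genes, the median was -0.60 relative to all genes and camera gave adjusted p = 2.49e-17 (adjusted p = 0.227 with an estimated correlation). All 8 carboxylesterases (0.00044) were below their before-exposure level, 3 of them past the threshold adjusted over the list alone. Fat body and haemolymph markers (0.00571), cytochrome P450 (0.0128), glutathione S-transferases (0.0309), odorant-binding and chemosensory proteins (0.0128), neuropeptides (0.0128), neurotransmitter receptors (0.0128), circadian clock (0.0201), learning and memory kinases (0.036), hormone signalling (0.0476) and histones (0.0483) were the other downward lists by camera. The unfolded protein response (0.00434), proteasome (0.00999), glycolysis and tricarboxylic acid cycle (0.0128), ribosomal proteins (0.0128), oxidative phosphorylation (0.0229) and photoreceptor markers (0.0286) were upward. With an estimated correlation the adjusted p of these 18 lists lay between 0.227 and 0.815, so none passed, and fry passed none. The other 14 lists had camera adjusted p-values from 0.133 (haemocyte markers) to 0.892, with voltage-gated ion channels at 0.254 and the gland list at 0.615, where camera pointed down while the mean and the median lay above 0 as deposited. Adjusted over the list alone, 5 cytochrome P450 genes fell and 1 rose, 3 lipid synthesis genes fell and 3 rose, and 3 gland genes fell and 1 rose. Camera pointed down for the UDP-glycosyltransferase and immune lists, whose mean was above 0. Without day 30 replicate 1 the 18 lists became 11, and without day 30 replicate 3 they became 10.

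Between the exposed days, days 30 and 10 differed in the most genes in the fit of all 11 libraries, with 844 past the threshold, 737 higher and 107 lower at day 30. With only the groups compared, day 20 against day 10 had more genes than day 30 against day 10. The royal jelly genes Mrjp7 (-4.38 ± 0.97 relative to the median gene), Mrjp2 (-3.93 ± 0.84) and Mrjp1 (-3.56 ± 0.87), LOC725215 (Acph-1, -3.61 ± 0.72) and LOC411186 (-3.13 ± 0.41) fell. LOC411420 (adenosine receptor A2b, 1.65 ± 0.34), LOC413984 (serine-rich adhesin for platelets, 1.36 ± 0.27), LOC409897 (1.32 ± 0.28), LOC410497 (1.29 ± 0.41) and LOC551071 (bromodomain adjacent to zinc finger domain, 1.24 ± 0.27) rose, with adjusted p between 0.0154 and 0.041 over the 10 genes. Of the 1500 genes called at day 10 against before exposure, 715 were called here, all in the opposite direction. Independent lists would share 127.2 in opposite directions and unchanged simulated groups 0.02. Both comparisons use the same day 10 libraries with opposite signs, however, which by itself favours opposite directions. The changes of the 2 comparisons correlated across genes with r = -0.833, and with -0.599 in unchanged simulated groups. The shared calls therefore do not by themselves show a return toward the level before exposure. With limma the count was 0 without day 10 replicate 2 or day 30 replicate 3 (832 and 1825 genes at an unadjusted p of 0.05). It was 15 without day 30 replicate 1, 313, 371 and 450 without day 20 replicates 3, 2 and 1, 406 and 473 without before-exposure replicates 3 and 2, and 55 with median-of-ratios scaling, 14 of them higher (25.5% against 87.3% as deposited).

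Day 20 differed from day 10 in 8 genes. The microtubule protein LOC725131 (futsch, 0.93 ± 0.16) and LOC411396 (neprilysin-4, a peptidase, 0.91 ± 0.16) were higher at day 20. LOC551094 (a fatty-acid amide hydrolase, -2.02 ± 0.30), LOC100578733 and LOC411564 (both described as nose resistant to fluoxetine protein 6, -1.80 ± 0.27 and -1.72 ± 0.25), LOC411983 (a putative fatty acyl-CoA reductase, -1.59 ± 0.22) and LOC409852 (SPT20 homolog, -1.28 ± 0.19) were lower, all with adjusted p = 0.044, as was LOC409638, a fatty acid elongase outside the naming rule. The count was 549 without day 10 replicate 3, 75 without day 30 replicate 2, 15 without before-exposure replicate 1, 4 without day 20 replicate 1 and 1 without day 10 replicate 2. With limma it was 0 without before-exposure replicate 2, day 20 replicate 2 or day 30 replicate 3 (1579, 1424 and 1537 genes at an unadjusted p of 0.05), and 0 with a pseudocount of 0.1 (1650 genes). Day 30 against day 20 had no gene past the threshold with limma and 503 at an unadjusted p of 0.05, and 1 without before-exposure replicate 1. LOC411186 (9.17 ± 4.49 to 1.35 ± 1.04 FPKM, adjusted p = 0.558), Obp3, an odorant-binding protein (54.3 ± 7.77 to 22.6 ± 8.13 FPKM), LOC409602 (-0.94 ± 0.19), Mrjp9 (-1.52 ± 0.29) and Mrjp7 (-3.68 ± 0.87) were the downward values with the smallest p. LOC412578 (a Mediator subunit, 0.92 ± 0.23), LOC412449 (caltractin, 2.47 ± 0.58), LOC100576784 (high mobility group B protein 6, 0.68 ± 0.18), LOC725011 (COX18, 0.64 ± 0.19) and LOC413763 (hydroxymethylglutaryl-CoA synthase 1, 0.59 ± 0.18) were the upward ones.

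With limma, no gene was called in the same direction at 2 or more of the 3 exposed days against before exposure. The 0 calls at days 20 and 30 fixed this, so it does not show that the days changed different genes. Independent lists of these sizes would share 0, and unchanged simulated groups shared 0.02 genes for days 10 and 20 and 0 for the other pairs. Of the 1326 genes lower at day 10, 98.5% were below before exposure at day 20 and 85.2% at day 30. Of the 174 higher genes, 82.8% and 94.3% were above it, though all these changes share the before-exposure libraries. The overlap was 1 without before-exposure replicate 1 or 2 or day 30 replicate 3, 4 without day 20 replicate 1 and 12 without day 30 replicate 2. The changes at days 10 and 20 correlated across genes with r = 0.613, where simulated unchanged groups sharing the same before-exposure libraries gave 0.444. For days 10 and 30 the values were 0.543 and 0.448, and for days 20 and 30 they were 0.598 and 0.501. The covariances of the 3 pairs were 0.0892, 0.079 and 0.0481 against 0.025, 0.0253 and 0.0252 simulated, an excess of 0.0642, 0.0538 and 0.0229. The 3 before-exposure libraries cannot be split into parts of 2 libraries each, so part of the excess may come from sharing them, and genes are not independent replicates. With the 3 exposed days averaged, 151 genes differed from before exposure, 25 higher and 126 lower, a count that moved by more than 1.5 times with each library left out. It was 706 without day 10 replicate 3, 82, 36 and 61 without day 30 replicates 1, 2 and 3, 3, 6 and 3 without day 20 replicates 1, 2 and 3, 2 without day 10 replicate 2, 1, 7 and 1 without before-exposure replicates 1, 2 and 3, and 1 with median-of-ratios scaling.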

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

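Tests chosen only after the result was seen are those of the gland makeup and gland spread, of the replicate number, of transcript length, of day 10 replicate 3 between separate libraries, of the gland and mitochondrial levels as covariates and of the muscle genes varying together, while the other tests of this part were set before. Sampling times differed from each other in a direct test, which does not separate exposure from elapsed time: 844 genes between days 30 and 10 and 8 genes between days 20 and 10 passed with limma. The 844 were 0 without day 10 replicate 2 or day 30 replicate 3 (832 and 1825 at an unadjusted p of 0.05), 15 without day 30 replicate 1, 313, 371 and 450 without day 20 replicates 3, 2 and 1, and 406 and 473 without before-exposure replicates 3 and 2. The 8 were 549 without day 10 replicate 3, 75 without day 30 replicate 2, 15 without before-exposure replicate 1, 4 without day 20 replicate 1, 1 without day 10 replicate 2, and 0 without before-exposure replicate 2, day 20 replicate 2 or day 30 replicate 3 (1579, 1424 and 1537 at an unadjusted p of 0.05). The values below are log2 changes as deposited, not relative to the median gene. Between days 30 and 10, LOC411420 (adenosine receptor A2b) changed by 1.87, LOC413984 by 1.57, LOC409897 (a multidrug resistance-associated protein) by 1.53, LOC410497 (G protein beta) by 1.5 and LOC551071 by 1.46. Mrjp7 changed by -4.17, Mrjp2 by -3.72, LOC725215 (Acph-1) by -3.40, Mrjp1 by -3.35 and LOC411186 (synaptic vesicle glycoprotein 2C) by -2.92. Between days 20 and 10, LOC725131 (futsch) changed by 1.02, LOC411396 (neprilysin-4) by 1.00, LOC551094 by -1.93, LOC100578733 by -1.71, LOC411564 by -1.63, LOC411983 by -1.5 and LOC409852 by -1.19. Single libraries in these groups of 2 or 3 were not tested as outliers.

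Royal jelly transcripts were higher at day 10. If a gland source of fixed makeup were present in differing amounts, the royal jelly proteins and the gland enzymes would shift together. The mean log2 level of Mrjp1 to Mrjp5 and Mrjp7 shifted by 4.29 ± 1.11 (SE) and that of Hbg3, alpha-amylase and glucose oxidase by 1.62 ± 0.83. The difference was 2.67 ± 0.81 (2.05 ± 0.68 with Mrjp6, which did not rise). In single libraries the first level less the second was -4.14, -1.64 and -1.91 in before-exposure replicates 1, 2 and 3. It was -0.38 and 0.59 at day 10, so the size of the shift leans on before-exposure replicate 1. These values speak against an unchanged source as the whole cause unless the brain itself makes part of the enzyme transcripts. Gland-type transcripts differ in level between libraries of 1 time: the mean of these 9 genes ranged over 3.45 log2 units within day 30, with all 9 highest in day 30 replicate 2 (Mrjp1 at 25775 FPKM against 3205 and 6270 FPKM in replicates 1 and 3), in line with gland tissue left on some brains despite its removal in the protocol. The royal jelly sum was highest in replicate 2 at all 4 times, yet with the replicate number as a block the mean of the 9 genes still shifted by 2.95 ± 0.65 (3.40 ± 0.95 without it, and 3.13 ± 1.09 without before-exposure replicate 1), which argues against the number as the whole cause. A shift of the gland toward royal jelly proteins, as between foraging and nursing bees, may add to it, and whether it would follow exposure, elapsed time or the bees collected, whose age and task the labels do not give, remains open.

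Of the genes tested, 1326 were lower at day 10, 87 of them among the 151 genes of the 5 neuronal lists (57.6% against 16.9% of all genes), though none of these lists passed with an estimated correlation (adjusted p = 0.462 to 0.514). The lower genes had a median of -0.65 relative to all genes in day 10 replicate 2 and of -0.41 in replicate 3, so the fall was larger in replicate 2. The median in replicate 3 decides nothing, as that library helped to choose the genes. A fit without either of the 2 leaves 1 library at day 10 and cannot decide it. Without before-exposure replicates 3 and 1, 917 and 958 genes passed with limma against 1500 with all libraries. Genes chosen as lowest in replicate 2 against 2 before-exposure libraries, however, had medians of -0.52, -0.23 and -0.32 relative to all genes in replicate 3 against the third, which argues against 1 library as the whole cause, while loss of long transcripts stays open without transcript lengths, with 14 of 14 neuropeptide precursors lower (median -0.51) but ribosomal proteins at a median of 0.34. A varying share of gland RNA stays open: across the lower genes, the slope on the royal jelly level within sampling times correlated with the change at day 10 at r = 0.33, with 5 of 100 permutations as high, just at the bound set beforehand, and with that level, of whose variance 70.6% lies between sampling times, as a covariate the median change went from -0.72 (median SE 0.17) to -0.47 (0.27) and 0 genes passed with limma (782 at an unadjusted p of 0.05). Library quality stays open for part of it: with the mitochondrial level as a covariate the median change was -0.53 (0.19) and 2 genes passed (1429 at an unadjusted p of 0.05), while the channel list went from -0.61 ± 0.15 to -0.33 ± 0.10 relative to the median gene, and an effect of exposure or of elapsed time was not tested apart from these.

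Muscle transcripts as a list were lower at days 20 and 30 by camera at the preset correlation, while 0 of 26 genes passed over all genes. With an estimated correlation camera did not pass the list (adjusted p = 0.446 and 0.227), and neither did fry (adjusted p = 0.105 and 0.117). Levels of the muscle genes also varied together within sampling times, with a mean pairwise correlation of 0.41 against a median of 0.146 in 1000 random lists. Other lists varied together more, such as ribosomal proteins (0.699), heat shock proteins (0.55) and voltage-gated ion channels (0.535). The correlation therefore cannot tell differing amounts of muscle on the dissected brains from a shared change within cells. The high level in before-exposure replicate 3 is not the whole cause, as the median without it was -0.32 relative to all genes at day 20 and -0.46 at day 30. TpnCIIIa (a troponin C), LOC409881 (a myosin regulatory light chain) and LOC410371 (a calcium-transporting ATPase), the most abundant genes of the list, stood at 102, 84.3 and 81.3 FPKM before exposure, 81.0, 55.9 and 66.2 FPKM at day 20 and 74.5, 47.0 and 74.6 FPKM at day 30, and none of the 26 genes is in another list. The labels name no step that removes muscle, and a change within brain cells was not tested.

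Of 100 groupings of the 11 libraries, only the real one gave as many as the 1500 genes at day 10 (highest other 1258). The same held for the 151 genes of the averaged exposed days (highest other 2). The groupings with 1258, 632 and 323 calls also had the 2 day 10 libraries as their day 10 group, and the next highest gave 2. The rank at day 10 thus shows mainly that those 2 libraries stand apart. It cannot exclude a chance difference between the bees sampled, as separate colonies or pools are not stated. The 151 genes were 1 with median-of-ratios scaling and with no filter, and 1, 7 and 1 without before-exposure replicates 1, 2 and 3, so chance is not excluded for them either. For days 20 and 30 against before exposure and day 30 against day 20, the 10 possible splits are too few for a share under 0.05, with a real count of 0 and a highest other of 0 in each (limma, with 774, 562 and 503 genes at an unadjusted p of 0.05). For the gene lists at day 20 the real count was 17 and the highest other 13, and at day 30 they were 18 and 21, again with too few splits.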

How the results depend on the processing

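The alternatives with the gland level or the mitochondrial transcript level as a covariate, and for the gene lists also median-of-ratios scaling, were chosen after seeing the data, as were the tests of the lower genes over all genes and of the channel list after rescaling. Depth limits no value in a known way, since FPKM keep no read counts, and with 2 or 3 libraries per group the spread between libraries sets the precision. Of the values of the genes named at day 10 against before exposure, taken over all alternatives, 1695 kept direction and side of the threshold, 523 lost the call and 6 turned. All 6 turned with the gland level as a covariate, to -0.46 for Mrjp3, which is itself part of that level, -0.98 for LOC725017, -1.52 for LOC413083, -1.65 for LOC406105, -0.63 for LOC725051 and -0.018 for A4. For day 20 and day 30 against before exposure 204 and 215 values stayed and 26 and 15 passed the threshold, for day 20 against day 10 84 stayed and 77 lost the call, for day 30 against day 10 143 stayed and 87 did, and for day 30 against day 20 218 stayed and 9 passed the threshold. No alternative turned a named gene in these comparisons. The cause was not tested for the changes in counts below, except where fewer genes tested or fewer libraries are the alternative itself.

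At day 10 against before exposure (1500 genes) the count was 777 with median-of-ratios scaling, 862 with quantile normalization, 931 with only the groups compared, 274 at 2-fold or more and 0 with the gland level as a covariate, where limma gave 782 genes at an unadjusted p of 0.05. Of the 1326 lower genes 466 were also called lower with median-of-ratios scaling, or 35.1%. This share met the bound set beforehand for dilution by a few very abundant transcripts. A lost call does not show that dilution made it, however, so the share cannot decide. In the test over all genes after rescaling, chosen after seeing the data, 466 genes were called lower. That argues against dilution as the whole cause for those 466, as does a median of -0.65 for the voltage-gated ion channels. For the other lower genes dilution stays open: the median change of all 1326 went from -0.72 (median SE 0.17) to -0.52 (0.16) as the median gene moved from -0.18 to 0.02, a shift set by the scaling, and calls ended with it. At day 20 against before exposure (0 genes) the count was 31 with array quality weights and 1 with only the groups compared, and at day 30 (0 genes) it was 39 with weights, 1 with only the groups compared and 1 with the gland covariate. For day 20 against day 10 (8 genes) it was 0 with a pseudocount of 0.1 and with no filter (limma, 1650 and 1792 genes at an unadjusted p of 0.05), 28 with a pseudocount of 5, 24 with a mean of at least 5 FPKM, 32 with median-of-ratios scaling, 28 with quantile normalization, 20 with weights, 26 with a robust fit, 5 with the gland covariate and 56 with only the groups compared. Day 30 against day 20 (0 genes) gave 14 with weights, 1 with the gland covariate and 1 with only the groups compared. Day 30 against day 10 (844 genes) gave 501 with no filter, 55 with median-of-ratios scaling, 150 with quantile normalization (65 higher and 85 lower), 1517 with weights, 7 with the gland covariate, 15 with only the groups compared and 128 at 2-fold or more. At day 10 quantile normalization gave 313 higher and 549 lower genes. The mean of the exposed days (151 genes) gave 87 with a pseudocount of 0.1, 1 with no filter, 289 with a mean of at least 5 FPKM, 1 with median-of-ratios scaling, 4 with quantile normalization, 348 with weights, 26 at 2-fold or more, and 0 with the gland covariate (limma, 612 at an unadjusted p of 0.05). The overlap between days (0 genes) was 31 with weights. With the mitochondrial covariate 2 genes were called at day 10, 0 for day 20 against day 10 (limma, 1291 at an unadjusted p of 0.05), 5 for day 30 against day 10 and 1 for the mean of the exposed days.

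Lists called at day 10 (17), day 20 (17) and day 30 (18) became 0, 0 and 0 with an estimated correlation, where 1, 2 and 4 lists had an unadjusted p under 0.05, and 9, 2 and 0 with fry. With the gland covariate 6 lists were called at day 10 (1 up and 5 down), 12 at day 20 (1 up and 11 down, against 11 and 6 without it) and 14 at day 30 (2 up and 12 down), and with quantile normalization and with the mitochondrial covariate 11 each at day 20.

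Over all genes the replicate numbers did not pair the libraries: of 15 same-numbered pairs 3 had deviations correlated above 0.1 (range -0.241 to 0.313), and 4 of 11 libraries correlated best with their own number. The royal jelly sum and LOC413083, LOC725017, LOC406105 and LOC725051 did go with it, all highest in replicate 2 at each time. With the number as a replicate block 1220 genes were called at day 10, 11 at day 20, 0 at day 30, 6 for day 20 against day 10, 0 for day 30 against day 20, 414 for day 30 against day 10, 274 for the mean of the exposed days and 7 in the overlap, and 16, 17 and 16 lists.

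With each library left out in turn, the counts of genes ranged from 2 (without day 10 replicate 2) to 1696 (without day 30 replicate 1) at day 10, 0 to 14 at day 20 and 0 to 7 at day 30 against before exposure. They ranged from 0 to 549 for day 20 against day 10, 0 to 1 for day 30 against day 20, 0 to 1247 for day 30 against day 10, 1 to 706 for the mean of the exposed days and 0 to 12 for the overlap. Lists ranged from 13 to 21 at day 10, 8 to 19 at day 20 and 10 to 18 at day 30. Where a day 10 library is left out, the remaining one is assumed to vary like the other groups.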

Other observations

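The genes named here were chosen after their values were seen. LOC406093 (apisimin), a small protein of royal jelly, stood at 5040 to 9537 FPKM before exposure, at 46747 and 78596 FPKM at day 10 (log2 change 3.02 ± 0.77, SE, adjusted p = 0.0191 with limma), and at 39590 FPKM in day 30 replicate 2 against 8769 and 9223 FPKM in day 30 replicates 1 and 3. Def1 stood at 483 to 798 FPKM before exposure, 5584 and 3254 FPKM at day 10, and 3817 FPKM in day 30 replicate 2 against 503 and 726 FPKM. Mrjp8, of the royal jelly protein family, stood at 5.04 to 8.89 FPKM in all 11 libraries (log2 change 0.05 ± 0.22 at day 10, adjusted p = 0.902), and the venom protein LOC503505 stood between 3050.4 and 3947 FPKM in all 11.

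LOC725114 and Hsc70-4 were high in single libraries of 2 or more sampling times. LOC725114, a chymotrypsin inhibitor, stood at 2201 FPKM in day 10 replicate 2, 1326 FPKM in day 20 replicate 3 and 1786 FPKM in day 30 replicate 2, and between 124 and 283 FPKM in the other 8 libraries. Hsc70-4, a heat shock cognate that cells generally use at high level, was listed at 194 FPKM in day 20 replicate 1 and 66.3 FPKM in day 30 replicate 1 and at 1.28 FPKM or less in the other 9, where 2 libraries list it at 0; values this low for such a gene can be failed estimates of the pipeline. Lop1, the long wavelength opsin of the eye, stood at 1159 FPKM in day 20 replicate 1 against 381 and 323 FPKM in day 20 replicates 2 and 3, 547 to 742 FPKM at day 30 and 182 to 310 FPKM before exposure (log2 change at day 30 1.35 ± 0.39, adjusted p = 0.325).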
